A study of Arabidopsis thaliana with 5 samples.

How the data were processed

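Arabidopsis thaliana seedlings of 6 days were studied with 1 5'GRO-seq, 2 GRO-seq and 2 RNA-seq libraries. The deposited table lists transcribed units with TAIR10 coordinates and 3 value columns, and 0 further columns of values per sample were left aside. Per the file headers, the first column gives the GRO-seq FPKM of each unit, computed by the authors. Per the file headers, the other columns give the deposited GRO-seq and RNA-seq signal as reads per unit scaled to 10 M mapped reads, with header factors of 0.73 and 0.52. Per the submitters' processing notes, STAR and HOMER 4.8 were used with the TAIR10 build; the STAR version is not given in the sources used here. Whether the values of an assay come from 1 library or from both is not given in the sources used here, nor are strand use and the treatment of reads with several matches. The columns carry no replicate, and each is treated as the authors' value for its assay.

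All values of the GRO-seq and RNA-seq signal columns, 100% of each, were within 0.02 of a whole number of reads once divided by the fitted worth of 1 read. This worth was 0.732 in GRO-seq and 0.522 in RNA-seq, and reads and total mapped reads were recovered from it. The FPKM column was 0 in 373 units, of which 368 held GRO-seq reads, and differed from the value recomputed from the reads by over 2% in 2 others. Ratios were therefore taken from the reads per 10 M. The transcript identifier differed from the annotated gene in 97 units, so the annotated gene and the coordinates were used in its place.

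The design written before the data were examined assumed counts or normalized values per library. The table gives 1 value per assay, so no test was run and no p-value is given. Ratios were log2((GRO-seq + 1)/(RNA-seq + 1)), for units with at least 1 read per 10 M in either assay. The pseudocount draws the ratios of low units toward 0. It lies below the floor of 3 RNA-seq reads (1.57 per 10 M), so units at 0 RNA-seq reads have larger ratios with it than at the floor, and class medians are given both ways. Exact Clopper-Pearson 95% intervals of the ratio were computed from the recovered reads without the pseudocount, and the floor was 3 reads. These compare the sequenced libraries, not conditions. The count of genes whose whole interval lay beyond 2-fold was added as an alternative after seeing the data.

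Gene structure and names came from the RefSeq annotation of the TAIR10.1 assembly, joined by locus and position; its nuclear chromosomes matched the units' coordinates. Of 9200 units, 9181 had their annotated gene in this reference. Of 8879 gene units, 8875 overlapped a reference gene on their strand and were named by the gene sharing the most bases, which was the authors' gene in 98.6%. Gene units among the 8879 without such an overlap kept the authors' gene. Besides the 8879, 5 gene units had no gene on their strand in the authors' annotation and were left out. Where several units had the same gene, the unit sharing most bases was kept. A unit overlapped 2 or more protein-coding genes on its strand in 1860 cases (20.9%), and its reads were not divided among them.

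The 15 lists of genes were fixed at the same stage. They covered light-harvesting and photosystem proteins, carbon fixation enzymes, cytosolic ribosomal proteins, histones, Aux/IAA, SAUR and JAZ genes, touch and early stress genes, heat shock genes, circadian clock genes, microRNA target genes, reference genes, root markers, guard and myrosin cell markers, and seed storage genes. Genes of the chloroplast and mitochondrial chromosomes were not analysed here. Lists were measured only in part, since a gene without a unit has no value. If units were picked for GRO-seq signal, members with little of it would be missing. That would raise the ratios of a list. Measured were 24 of 43 light-harvesting and photosystem genes, 12 of 17 carbon fixation, 37 of 88 ribosomal protein, and 12 of 20 touch and early stress genes. The median of each list was placed among 10000 random lists of the same size matched in 20 bins of mean level, and the percentile describes these values. The matching was tried on simulated data of 8880 units, with lists of 20 genes in the comparison of GRO-seq with RNA-seq. There, 98% of lists shifted 2-fold, 100% of lists shifted 4-fold and 6% of unshifted lists fell outside the middle 95%. The simulated ratios varied independently from unit to unit, with no trend with level put in. Members of the real lists may vary together, so the 6% is no error rate for their percentiles.

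Genes were named by a rule fixed beforehand, without its conditions on p-values and replicates, which could not apply. The rule took the 6 highest and 6 lowest log2 ratios among genes above the median of mean level. For each list with at least 5 measured members it took the member with the highest mean level and the member with the largest absolute ratio. ACT2 and UBQ10 were added as reference genes. Genes named outside this rule are said to be so.

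Alternatives fixed with the design and run here were no filter, a minimum of 5, a pseudocount of 0.1, nuclear chromosomes only, and only genes that overlap no other annotated gene. Alternatives chosen after seeing the data were length-scaled reads, units over 1 gene on their strand, leaving out units with an FPKM of 0, the counting interval, and random lists matched on level, intron class and gene length or on the GRO-seq value, the former also for families of genes with the same product name. Planned fits that need values per library were not run. Alignments of units to ribosomal RNA genes used BLAST+ 2.17.0. Computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.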

Results

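Nascent and mature RNA of Arabidopsis thaliana were measured in 6-day-old seedlings. The series holds 5 libraries. There are 2 GRO-seq libraries, in which RNA polymerases run on in isolated nuclei so that newly made RNA is sequenced. There are 2 RNA-seq libraries of polyadenylated RNA, and 1 library of capped nascent RNA (5'GRO-seq), whose values were not analysed here. The deposited table gives 1 value per assay for each of 9200 transcribed units on the 5 nuclear chromosomes of the TAIR10 build. No replicate values were used here, so every difference below describes the authors' values for these assays and has no replicate check. The steps between values put 1 GRO-seq read at 0.732 per 10 M mapped reads (M, mega), which gives 13.7 M mapped reads, and 1 RNA-seq read at 0.522, which gives 19.2 M. Units held 5.38 M GRO-seq reads (39.4%) and 11.2 M RNA-seq reads (58.7%). The median unit held 298 GRO-seq reads and 451 RNA-seq reads. Intervals given for a gene are exact 95% intervals of the ratio of its reads, and those for a list or class are exact 95% intervals of the median. Those for genes cover counting error only.

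The comparison of GRO-seq with RNA-seq asked how new transcription related to the standing pool of messenger RNA. Genes of photosynthesis had far lower values in GRO-seq than in RNA-seq, and genes that respond to touch and early stress had far higher ones. The photosystem I antenna gene LHCA4 had 14577 reads per 10 M in GRO-seq and 91145 in RNA-seq. The stress transcription factor WRKY40 had 866 and 7.83. Across 9196 units the log2 values correlated with a Pearson r of 0.75 and a Spearman rho of 0.78. These are taken across units, which are not independent replicates. Reads were not scaled to length here, so the unit length shared by both assays may raise both coefficients. Of the 8848 genes represented by a unit, 1449 were over 2-fold higher in GRO-seq and 1829 over 2-fold lower. The counting interval of the ratio lay wholly beyond 2-fold in 1054 of the former and 1414 of the latter, which compares the sequenced libraries and not conditions. The median log2 ratio of these genes was -0.12. All of these values rest on scaling to all mapped reads, of which 39.4% in GRO-seq and 58.7% in RNA-seq lay in units. Scaling to the reads in units would raise the ratios and was not run. The balance of higher and lower genes depends on this choice, and on which genes have a unit. When GRO-seq reads were scaled to unit length and RNA-seq reads to exon length, the median of all genes moved to -0.84. Of the genes over 2-fold apart, the share that was higher in GRO-seq then went from 44.2% to 18.8%. Units hold introns and run past gene ends, so this scaling lowers most genes by construction.

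**Figure D1:**
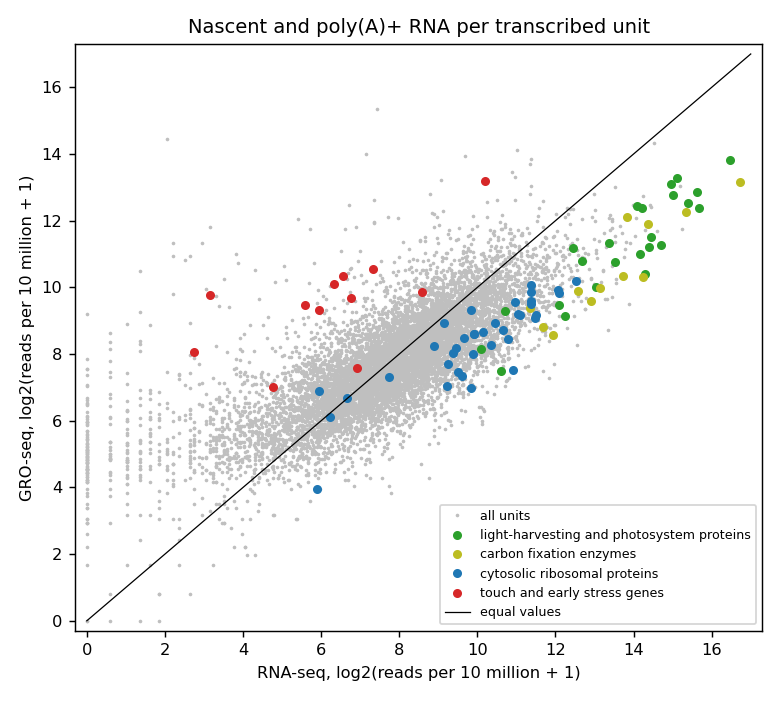
Each point is a transcribed unit, with its RNA-seq value on the horizontal axis and its GRO-seq value on the vertical axis, both as log2 of reads per 10 M plus 1. The 24 light-harvesting and photosystem genes lie below the line of equal values, and all 12 touch and early stress genes lie above it.

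Light-harvesting and photosystem genes, which encode the antenna and reaction centre proteins of the chloroplast, were over 2-fold lower in GRO-seq in all 24 measured members. Their median log2 ratio was -2.70 (95% interval -3.10 to -1.89). It lay at percentile 0 of 10000 random lists of the same size matched on mean level, whose middle 95% ran from -1.48 to -0.20. PSAN, a photosystem I subunit, had the largest difference, with 1354 in GRO-seq and 19964 in RNA-seq (log2 ratio -3.88, interval -3.95 to -3.82). LHCA4 had the highest mean level, at a log2 ratio of -2.64 (interval -2.67 to -2.62). Carbon fixation enzymes were lower in all 12 measured members, with a median of -3.11 (interval -3.38 to -2.47) at percentile 0. RCA, the rubisco activase, had 9081 in GRO-seq and 108498 in RNA-seq (log2 ratio -3.58, interval -3.60 to -3.55). RBCS3B, a small subunit of rubisco, had 1272 and 19397 (log2 ratio -3.93, interval -4.00 to -3.86). RBCS3B has near-identical copies beside it, so the division of reads among these copies is uncertain.

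Cytosolic ribosomal protein genes were also lower in GRO-seq, by over 2-fold in 30 of 37 measured members and within 2-fold in the other 7. Their median log2 ratio was -1.78 (interval -1.94 to -1.35), at percentile 0 of level-matched lists. RPS24B had 184 in GRO-seq and 1914 in RNA-seq (log2 ratio -3.37, interval -3.57 to -3.19). RPS9B, the member with the highest mean level, had 1179 and 5900 (log2 ratio -2.32, interval -2.40 to -2.25). Histone genes had a median of -0.94 (interval -1.25 to -0.31) at percentile 0.55, with 8 of 19 members over 2-fold lower and 2 over 2-fold higher. The linker histone gene H1.3 had 138 in GRO-seq and 927 in RNA-seq (log2 ratio -2.74). AT4G40030, a histone gene, had the highest mean level at 5106 and 8254 (log2 ratio -0.69), in a unit that overlapped 3 protein-coding genes. Histone genes share sequence with near-identical copies, so their values are uncertain. Against lists matched on intron class, gene length and 5 bins of level, the histone median lay at percentile 9.22, inside the random range. Level was matched more loosely there, so the change is not credited to structure alone.

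Touch and early stress genes were higher in GRO-seq by over 2-fold in 11 of 12 measured members. The median log2 ratio was 3.29 (interval 2.26 to 3.89), at percentile 100 of random lists whose middle 95% ran from -0.85 to 0.55. WRKY40 had the largest difference, with a log2 ratio of 6.62 (interval 6.06 to 7.63). TEM2, a transcription factor gene, had the highest mean level, with 9397 in GRO-seq and 1175 in RNA-seq (log2 ratio 3.00, interval 2.93 to 3.06), in a unit that overlapped 2 protein-coding genes. The cold-response factor gene CBF3 had 269 and 5.74 (log2 ratio 5.32), and the calmodulin-like gene TCH2 had 1299 and 93.9 (log2 ratio 3.78). WRKY46 was the member within 2-fold, at a log2 ratio of 0.67. CBF3, TCH2 and WRKY46 were chosen after their values were seen.

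Genes targeted by microRNAs had a median log2 ratio of 0.76 (interval 0.08 to 1.32), at percentile 100. High medians were not particular to this list. Some families of transcription factors had them too, such as myb genes (0.88, percentile 99.88) and NAC genes (0.74, percentile 98.49). The bHLH family did not (0.06, percentile 78.04). These families were chosen after their values were seen. Of 33 measured members, 11 were over 2-fold higher in GRO-seq, 1 was over 2-fold lower and 21 lay within 2-fold. The member that was lower was PHO2, a regulator of phosphate uptake, with 308 in GRO-seq and 2990 in RNA-seq (log2 ratio -3.27, interval -3.42 to -3.14). AGO1, the main Argonaute gene, had 2310 and 2138 (log2 ratio 0.11, interval 0.04 to 0.18). With length scaling, and the median of all genes held at -0.12, the AGO1 ratio turned to -0.22. The AGO1 unit overlapped 2 protein-coding genes.

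The auxin-induced SAUR genes had a median log2 ratio of 1.35 (interval 0.99 to 3.13) at percentile 99.2, with 7 of 9 members over 2-fold higher in GRO-seq. SAUR16 had 2219 in GRO-seq and 870 in RNA-seq (log2 ratio 1.35, interval 1.26 to 1.44). SAUR67 rested on 25 GRO-seq reads and 2 RNA-seq reads (log2 ratio 3.24, interval 2.13 to 7.25). SAUR genes lie in clusters of similar copies, so single values are uncertain. Against lists matched on intron class, gene length and 5 bins of level, the SAUR median lay at percentile 73.7, inside the random range. Aux/IAA repressor genes had a median of 0.01 at percentile 74.95, with 3 of 15 members over 2-fold higher and 4 over 2-fold lower. Relative to all genes the median was 0.13, and 0.49 over the 13 members whose units overlapped 1 gene. IAA8 had 442 and 3714 (log2 ratio -3.07), while IAA16, at the highest mean level, had 2610 and 3241 (log2 ratio -0.31).

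The 5 measured JAZ repressor genes of jasmonate response had a median log2 ratio of 1.13 at percentile 90.4 of level-matched lists, inside the random range. It lay at percentile 96.8 of lists matched on level, intron class and gene length, also inside, and at percentile 97.52 of lists matched on the GRO-seq value, just outside. Relative to all genes the median was 1.25, and 2.497 over the 4 members that overlap no other annotated gene. JAZ12 had 441 in GRO-seq and 394 in RNA-seq (log2 ratio 0.16, and -0.40 with length scaling and the median of all genes held at -0.12). JAZ7 rested on 44 GRO-seq reads and 2 RNA-seq reads (log2 ratio 4.02, interval 3.01 to 8.04). Circadian clock genes had a median of -0.36 at percentile 58.4, inside the random range. The morning clock gene CCA1 had both the highest mean level and the largest difference, with 2253 and 14068 (log2 ratio -2.64, interval -2.70 to -2.59). The units of CCA1 and ACT2 each overlapped 2 protein-coding genes. Over the 4 clock genes whose units overlapped 1 gene, the median relative to all genes was 0.10, against -0.24 for all 7. Reference genes had a median of -0.50 at percentile 47.7. Relative to all genes it was -0.38, and the alternatives placed it between -0.74 (8 genes that overlap no other annotated gene) and -0.07 (7 genes whose units overlapped 1 gene). The actin gene ACT2 had 2959 in GRO-seq and 11801 in RNA-seq (log2 ratio -2.00, interval -2.04 to -1.95). The polyubiquitin gene UBQ10 had 20497 and 23410 (log2 ratio -0.19, and 0.088 with the same scaling as for JAZ12). The 4 measured heat shock genes had a median of 0.35 at percentile 81.3. The list of guard and myrosin cell markers had 1 measured member, KAT1 (log2 ratio -0.05), named here outside the rule. The lists of root markers and seed storage genes had 0 measured members each.

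**Figure D2:**
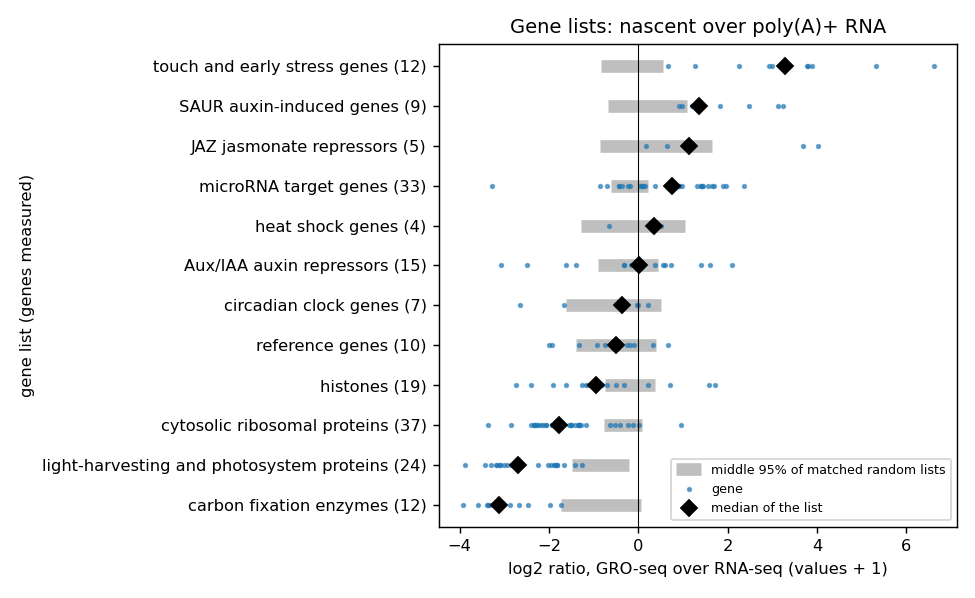
Rows are the gene lists with at least 4 measured genes, and the horizontal axis is the log2 ratio of GRO-seq over RNA-seq. Small points are genes, diamonds are list medians, and grey bars are the middle 95% of 10000 level-matched random lists. The touch and early stress median of 3.29 lies right of its bar and the carbon fixation median of -3.11 lies left of its bar.

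Among genes in the upper part of the range of mean level, the highest ratios belonged to AT2G01008, AT2G35750 and UBP27. AT2G01008 (unit on chromosome 2, 1871 to 3291, plus strand) had 22180 in GRO-seq and 3.13 in RNA-seq (log2 ratio 12.39, interval 11.67 to 14.24). Its unit held an annotated microRNA gene, AT2G03855 (2805 to 3176), and ended 415 bases before an annotated 18S ribosomal RNA gene. AT2G35750 (unit on chromosome 2, 15028495 to 15030319, minus strand) had 41975 and 172 (log2 ratio 7.93, interval 7.78 to 8.09), and its unit held 4 annotated snoRNA genes. The unit named for UBP27, a ubiquitin-specific protease (chromosome 4, 18304751 to 18306762, plus strand), had 16234 and 140 (log2 ratio 6.85, interval 6.68 to 7.04). That unit held 5 snoRNA genes and ended before the end of UBP27. AT4G29780, annotated as a nuclease, had 4217 and 41.8 (log2 ratio 6.62). NUDT4, a nudix hydrolase, had 3421 and 51.7 (log2 ratio 6.02), and AT1G32920 had 5622 and 103 (log2 ratio 5.75).

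**Figure D3:**
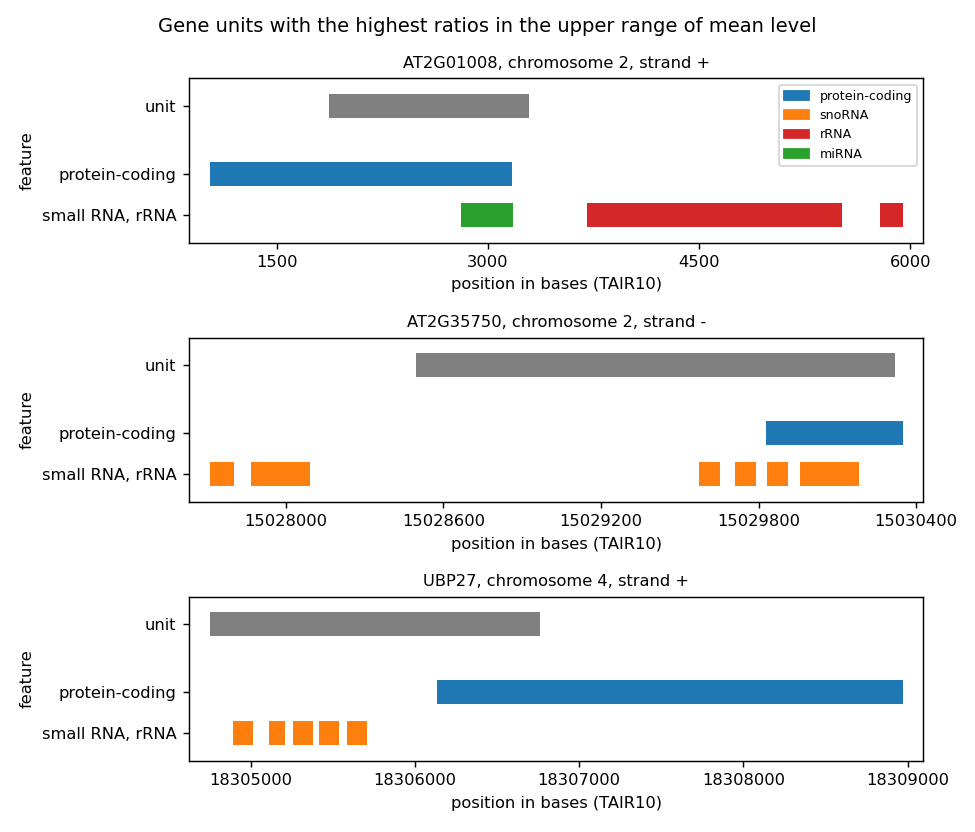
Each panel shows 1 unit in grey above the annotated genes on its strand, with the position in bases on the horizontal axis. The AT2G35750 unit spans 4 snoRNA genes, the UBP27 unit spans 5, and the AT2G01008 unit stops 415 bases before the 18S ribosomal RNA gene.

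The lowest ratios in the same range included DI19 and the metallothionein genes. DI19, a drought-induced gene, had 421 in GRO-seq and 10473 in RNA-seq (log2 ratio -4.63, interval -4.76 to -4.52). The metallothionein genes MT3 and MT2B had log2 ratios of -4.55 and -4.38, with RNA-seq values of 3628 and 15070. AT1G09310, a gene of unknown function, had 308 and 5960 (log2 ratio -4.27). MLP28 had 208 and 4023 (log2 ratio -4.27), and the late embryogenesis abundant gene AT3G17520 had 59.3 and 1105 (log2 ratio -4.20). MLP28 belongs to a cluster of similar genes, so its share of reads is uncertain.

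Noncoding units had higher ratios of GRO-seq to RNA-seq than protein-coding units, with far lower RNA-seq values. Across all units, 5 had 0 GRO-seq reads and 96 had 0 RNA-seq reads. Units may thus have been picked for GRO-seq signal, which would raise the ratios of noncoding and antisense units by selection. The same would hold for protein-coding units, and so for the gene lists. The median GRO-seq value was 76.1 in tRNA units, 223 in microRNA units and 231 in protein-coding units, and the median RNA-seq value was 0, 7.05 and 255. The 15 tRNA units had a median log2 ratio of 6.13 (interval 4.57 to 7.55), the 18 microRNA units 4.39 (interval 3.42 to 6.86), and the 99 other noncoding RNA units 1.42 (interval 0.89 to 1.80). Pseudogene units had a median of 1.00 and protein-coding units one of -0.14 (interval -0.17 to -0.11). With units without RNA-seq reads set to the floor of 3 reads, the tRNA median was 5.46 and the microRNA median 4.22. The microRNA precursor MIR159A had 2600 in GRO-seq and 3.65 in RNA-seq, a ratio of 711 (interval 345 to 1771). MIR156C, second by GRO-seq value, had 2196 and 126, a ratio of 17.5 (interval 15.3 to 20.0), and MIR167A had 1225 and 10.4. The tRNA unit with the highest GRO-seq value, at AT1G52860, had 330 and 1 RNA-seq read, a ratio of 633 (interval 113 to 25040). The tRNA unit at AT2G15950 had 315 GRO-seq reads and 0 RNA-seq reads, so it was at least 147-fold higher in GRO-seq against a floor of 3 reads, and the exact interval of its ratio began at 119. These units were chosen after their values were seen. Polyadenylated RNA libraries exclude most RNA without a tail, and the class named microRNA by the authors includes snoRNA units.

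Transcription antisense to genes was present in 264 units, with a median of 43.2 reads per 10 M in GRO-seq and 4.70 in RNA-seq. Their median log2 ratio was 3.00 (interval 2.61 to 3.29), or 2.94 with units at 0 set to the floor. The 16 units antisense at promoters had a median of 4.73 (4.18 with the floor), and the 36 unannotated noncoding units 4.40 (4.05 with the floor). For 123 antisense units the gene on the opposite strand also had a unit. The antisense median there was 45.4 and the sense median 451, and 8 antisense units had more GRO-seq reads than their sense unit. The antisense unit with the highest GRO-seq value, at AT2G11240, was lower in GRO-seq, with 626 against 1346 in RNA-seq. The second, at AT3G17890, had 615 in GRO-seq and 3 RNA-seq reads, a ratio of 393 (interval 134 to 1908), and its unit held a small noncoding RNA gene. The third, antisense to BCCP2, a subunit of a fatty acid synthesis enzyme, had 551 in GRO-seq and 50.1 in RNA-seq. All 3 were chosen after their values were seen.

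**Figure D4:**
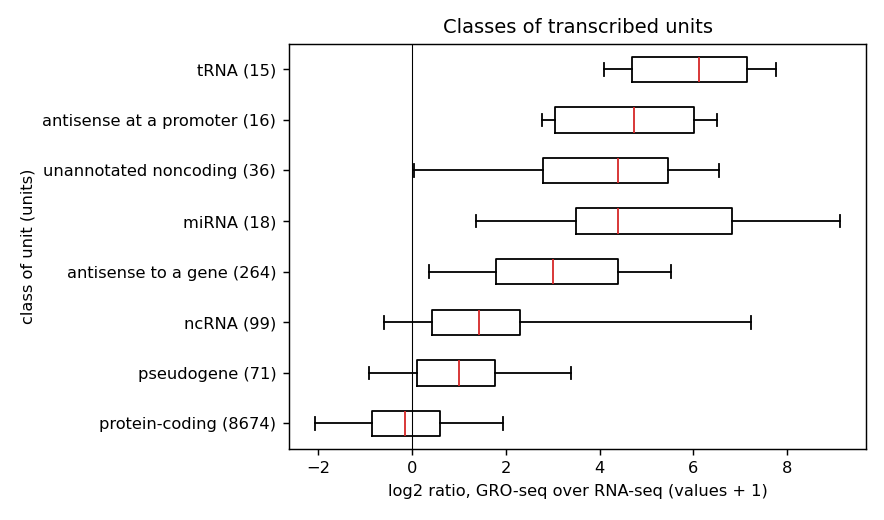
Boxes show the log2 ratio of GRO-seq over RNA-seq per class of unit, with the middle quartiles, the median in red and whiskers from percentile 5 to percentile 95. The protein-coding median is -0.14 and the tRNA median 6.13.

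Gene structure was compared because nascent RNA holds introns and mature RNA does not. The 1077 genes without introns had a median log2 ratio of 0.57 (interval 0.45 to 0.68), the 3512 genes with 1 to 4 introns -0.10 and the 4257 genes with 5 or more introns -0.22 (interval -0.26 to -0.20). With length scaling these medians were 0.12, -0.73 and -1.06. Genes in the shortest length quintile had a median of 0.07 and those in the longest -0.14. The GC quintiles, from lowest to highest, had 0.10, -0.16, -0.20, -0.19 and -0.10, so the ratio did not fall steadily with GC content. The difference between the highest and the lowest changed sign with length scaling. Spearman's rho across genes with the log2 ratio was -0.16 for intron number, -0.05 for gene length and -0.05 for GC content.

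Transcribed units ran past the annotated 3' ends of genes. Over 8639 protein-coding units the median unit ended 547 bases past the annotated end (interval 534 to 557), and 87.1% of units ended beyond it. For the 6788 units that overlapped 1 protein-coding gene, a set chosen after seeing the data, the median was 493 bases. In that set, units followed by a gene on the same strand ended 439 bases past (interval 428 to 450), and units followed by a gene on the opposite strand 554.5 bases past (interval 538 to 572). With at least 2000 bases to the next gene the values were 534.5 and 576. The distance was 331.5 bases in the lowest quintile of GRO-seq reads per base and 614 in the highest. In the lowest quintile 66.2% of units ended past the annotated end, against 95.9% in the highest. Reads per base is taken over the unit, whose length includes the stretch past the end. Units with few reads may also have been called short, so the trend does not decide how far transcription went. At the 5' side, the median unit of this set began 115 bases inside the annotated start. The closest transcription start given by the authors lay at a median distance of 29 bases, so the offset depends on the starts used. The limits of the units were set by the authors' calls, and the annotation used for gene ends was a later release on the same build.

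**Figure D5:**
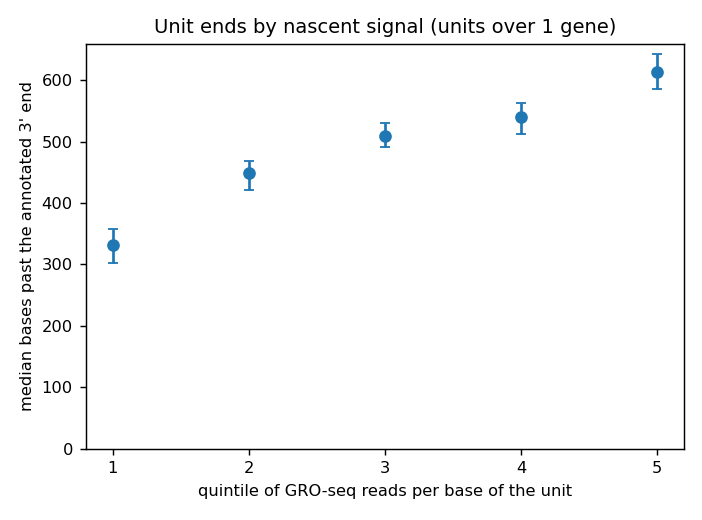
Points are the median number of bases between the annotated 3' end and the end of the unit, by quintile of GRO-seq reads per base, for units over 1 protein-coding gene. Bars are exact 95% intervals of the median, and the medians run from 331.5 to 614 bases. The called end of a unit may itself depend on its number of reads.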

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

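No paired analysis was possible because the columns carry no replicate. For the same reason the replicate block, leaving out single libraries, other size factors, other count tests, other set tests and the 5'GRO-seq comparisons were not run. Length scaling, units over 1 gene, units without an FPKM of 0, counting intervals and other matching were chosen after seeing the data. Of 95 list medians taken relative to all genes under alternatives, 93 stayed inside their main interval, or inside the range of their members for lists under 6 genes. Nuclear chromosomes only removed nothing. No filter and a minimum of 5 kept 8849 and 8842 genes against 8848, so these settings could hardly move a median. For lists under 6 genes, the median of a subset without length scaling always lies inside the range of its members. The 93 of 95 is therefore no measure of robustness. Length scaling lowers most genes by construction. With it, 918 genes were over 2-fold higher and 3956 over 2-fold lower in GRO-seq, the share higher being 18.8% against 44.2%. Relative to all genes, the ribosomal protein median was then -1.95 and the heat shock median 0.77. The difference between 5 or more introns and none was -1.17, and that between the highest and lowest GC quintile turned to 0.17. With the all-gene median held at -0.12, JAZ12, AGO1 and UBQ10 turned to -0.40, -0.22 and 0.088. Of 66 values of named genes under length scaling or the pseudocount of 0.1, 21 others moved outside their counting interval. Limited to genes overlapping no other annotated gene, 1205 of 5932 genes were over 2-fold lower, fewer because fewer genes were measured, and the longest minus the shortest length quintile was -0.36. Matched on level, intron class and gene length, the histone percentile was 9.22 and the SAUR percentile 73.7. Matched on the GRO-seq value, the JAZ percentile was 97.52. With a pseudocount of 0.1, Pearson's r was 0.73. Relative to all genes, the clock median was 0.10 over units with 1 gene. Such units ended 493 bases past the 3' end. Other causes were not tested. Units with few RNA-seq reads, such as tRNA units, were limited by depth.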

Other observations

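Families of genes with the same product name and at least 8 measured members were compared in the same way, after seeing the data. Of 126 families, 7 had a median in the uppermost 0.1% of level-matched random lists and 2 in the lowest 0.1%. By chance 0.252 would be outside if members of a family varied as independently as random genes. They need not, so this figure may be too low. Matched on intron class, gene length and 5 bins of level, 4 of these 9 families (thioredoxin, peroxidase, RRM and TIR-NBS-LRR) stayed in the same 0.1% tails. The other 5 left them, with EF-hand at percentile 99.45, LEA at 98.3, RING/U-box at 99.86, A20/AN1 at 99.56 and VQ at 96.2, inside the middle 95%. The 11 genes of the calcium-binding EF-hand family had a median log2 ratio of 1.53 (6 over 2-fold higher in GRO-seq, 1 lower), and the 8 genes of the VQ motif family, regulators that bind WRKY factors, had 1.89 (7 over 2-fold higher). The 17 TIR-NBS-LRR disease resistance genes had a median of 1.06, with 9 over 2-fold higher and 0 over 2-fold lower. The 12 LEA hydroxyproline-rich glycoprotein genes had 1.62 (7 higher, 0 lower). Members of the other families went both ways. The 94 RING/U-box genes had 0.43 (24 higher, 2 lower), the 62 RNA-binding RRM genes 0.30 (14 higher, 11 lower) and the 8 A20/AN1 zinc finger genes 0.99 (4 higher, 2 lower). Peroxidase genes lay on the other side with a median of -1.65 over 14 genes (8 over 2-fold lower), as did thioredoxin superfamily genes with -2.02 over 9 genes (6 lower, 2 higher). AT3G56880, of the VQ family, had 4429 in GRO-seq and 208 in RNA-seq, and the peroxidase gene PRXR1 had 802 and 10259. Both genes were named outside the rule, after their values were seen.

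In the weighing below, both matchings of random lists (on structure and on the GRO-seq value), length scaling, the comparison of stress with auxin genes, both counts of small RNA genes and the distance to ribosomal RNA were tests chosen after the result was seen. Touch and early stress genes were higher in GRO-seq by a median log2 ratio of 3.29. Gene structure and counting over whole units would place the list inside random lists matched on level, intron class and gene length, and it lay at percentile 100 of them. The list exceeded the SAUR and Aux/IAA lists by 2.48 (95% bootstrap interval 1.58 to 3.48), but these medians were known when the comparison was chosen and the Aux/IAA genes go both ways, so it does not decide on transcription induced while nuclei were prepared. That explanation and fast decay of these transcripts both stay open. The design names no group that would test a biological explanation.

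Photosystem and carbon fixation genes, joined, were lower in GRO-seq by a median log2 ratio of -2.81. Gene structure and counting over whole units is argued against by percentile 0 among lists matched on level, intron class and gene length. The joined list lay at percentile 0 of lists matched on the GRO-seq value. This does not decide on high level alone, since at a given GRO-seq value a high RNA-seq value lowers the ratio by construction. The joined list also lay at percentile 0 of lists matched in 20 bins of mean level (random range -1.29 to -0.29). Level was not matched within a bin, so high level alone stays open. The joined list had a median of 2196 reads per 10 M in GRO-seq, against 228 for all gene units. PSAE2, at 179, lay below the latter. These values argue against transcription of the list that was low compared with other genes. Stable messenger RNA and transcription lower at sampling than at other times may both apply, and no biological explanation was tested.

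Of the 20 units with the highest ratio, 17 held a small noncoding RNA gene on their strand, but 7 of the 20 are themselves microRNA or tRNA units, so this count decides nothing. Among the 20 protein-coding units with the highest ratio, 6 held such a gene, where the middle 95% of random sets of 20 protein-coding units reached at most 2. Because AT2G01008, AT2G35750 and UBP27 are among the 6 and their units had been mapped when the count was chosen, small noncoding RNA genes inside the unit stay open as a source of these reads, and the other 14 units held none. Sequence of the annotated ribosomal RNA genes in the unit is argued against for AT2G01008, AT2G35750 and UBP27. Of the bases of each, 0% aligned to these genes at 95% identity. Unannotated parts of the pre-ribosomal RNA, such as the stretch before the 18S gene, could not align, so the 0% does not bear on them. Pre-ribosomal RNA that covers the unit also stays open for AT2G01008. Its unit ended 415 bases before an 18S ribosomal RNA gene on its strand, a distance known beforehand. Only the annotated 18S and 5.8S genes were searched.

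It had been anticipated before the values were computed that genes with more introns would be higher in GRO-seq, with introns counted in nascent RNA. They were lower. Length scaling lowers intron-rich genes by construction, so its effect on the difference between genes with 5 or more introns and none (-48.6%, where a positive value would be a shrinkage) decides nothing.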
